A study of mouse gut metagenome with 36 samples.

How the data were processed

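Stomach bacteria of 36 male C57BL/6 mice were profiled by amplicon sequencing of the V3 and V4 regions of the 16S rRNA gene on an Illumina MiSeq, per the labels' protocols. Feed was sterile and the diets were those of the CTL, Salt, S+B and B groups, per the labels' protocols. Trimmomatic is named per the submitters' processing notes, with no version given there. The tools for OTU clustering, chimera removal and taxonomy, and the taxonomy database, are not given in the sources used here. The deposited values were raw counts of reads per OTU, with a lineage for each OTU. That they were counts was checked on the values, which were whole numbers with a different total in each of the 36 columns. Of these columns, 35 carried the name of a sample title. The column named (S+B)3 matched no title and the title (S+B)4 had no column, so that column was assigned to the S+B group alone and is called S+B unnumbered. All columns of values were used, and 0 were left out. No pair of columns was identical.

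Total counts per sample lay between 15150 and 38426, and no sample fell under the minimum of 1000 counts. A count of 0 in all of CTL or Salt allows a share of up to 0.00104% or 0.00139% (3 counts of the group's total). Shares of single samples carry 95% Wilson intervals. Ratios against a group with 1 to 3 counts carry 95% counting intervals, and those against a group with none are lower bounds against a floor of 3 counts over that group. The 25 OTUs annotated as chloroplast or mitochondria, with 0.385% of the 969734 counts, were left out because they can stem from plant or host organelles. They were kept only as the list of plant organelle DNA. Counts of the other 4081 OTUs, of which 1078 had a single count, were summed to genus by the deposited lineage. An OTU without a genus went to its lowest named rank, which gave 299 groups, 211 of them with a genus name.

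Groups were compared as Salt with CTL, S+B with Salt and B with Salt (main comparisons), and S+B with CTL, B with CTL and B with S+B (secondary). Genus and OTU counts were tested with edgeR 4.0.16 in R 4.3.3. One quasi-likelihood model held all 36 samples, with robust dispersion, TMM scaling and the filterByExpr defaults (minimum count 10, smallest group 7 samples), which left 65 genus-level groups and 374 OTUs. Fold changes are log2 with SE. A call is a Benjamini-Hochberg adjusted p under 0.05. The number of samples showing a direction is counted against the median of the comparison group.

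Shannon index and observed OTUs were averaged over 100 draws without replacement of 15149 counts per sample, the lowest total once organelle OTUs were removed. They were compared by two-sided permutation tests of the difference of means, exact where a group had under 10 samples and otherwise with 100000 resamples. The 12 p-values of the 6 pairs were adjusted together. The 4 phyla with a mean of at least 1% and the log2 ratio of Firmicutes to Bacteroidetes (1 count added to each) were tested in the same way in the main comparisons, as a family of 15. Composition was compared by PERMANOVA (vegan 2.7.1, 9999 permutations) on Bray-Curtis dissimilarity of OTU shares, with a test of spread around the group centres beside it.

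The 9 taxon lists were lactic acid bacteria, butyrate and other short-chain fatty acid producers among the Clostridia, gut Bacteroidales, Helicobacter and relatives, enterobacteria and other opportunist Gammaproteobacteria, salt-tolerant and skin or bedding Gram-positives, fibre- and mucin-responsive rodent gut genera, genera common as contaminants of DNA kits or water, and plant organelle DNA. Their summed shares were tested by permutation as log2 of the percentage plus 0.01, as a family of 27. The lists, comparisons, tests, main settings and the rule for named taxa were fixed before the data were examined. That rule takes the 10 genera with the highest mean share and, among called genera with a mean share of at least 0.1% in either group, the 10 largest changes in each direction per main comparison and 5 per secondary one. It adds every list member called in a main comparison and the 3 OTUs per direction with the smallest p. Taxa with no name below phylum were counted but not named.

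Movement back towards CTL was measured by the correlation and covariance across genera of the fold changes of Salt against CTL and of each buckwheat group against Salt. Because both share the Salt samples, the same values were taken from 100 simulations of unchanged groups and from 100 random divisions of the Salt samples. Correlations across samples were computed on log2 shares with 0.01 added.

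The alternatives were DESeq2 1.42.0, library size without TMM, no filter on low counts (for OTUs, at least 10 counts in all), organelle OTUs kept, the centred log ratio (0.5 added) with limma 3.58.1, a fit of the compared groups alone, and the replicate number as a block. For diversity they were no rarefaction and leaving out OTUs under 10 counts. For composition they were Jaccard, Aitchison and genus-level dissimilarity. For phyla and lists they were another scale, ranks or a pseudocount of 0.1, and for movement back towards CTL only genera of at least 0.1%. Alternatives chosen after seeing the data left out each sample in turn, the unnumbered S+B sample, or 4 set-aside samples with high shares of Clostridium, Turicibacter or Devosia (CTL 8, Salt 6, S+B 5 and B 5; CTL 5, with most counts in Lactobacillus, was kept). Others took the numbers 1 to 5 and 6 to 10 separately, as a block, or as a random block within groups. The comparison of S24-7 OTUs within their family was also chosen after seeing the data.

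The model was tested on simulated data with the sample sizes and depths of Salt against CTL, in 20 draws. Among 65 genera it recovered 32.1%, 86.4% and 97.5% of changes of 4-fold, 16-fold and 64-fold and called 1.8% of unchanged genera. Among 374 OTUs it recovered 39.1%, 92.3% and 99.4% and called 1.4%. Simulated changes went up and down in equal number, so these rates do not cover an unbalanced change. The real TMM factors averaged 0.684 in CTL and 1.543 in Salt. The permutation test of 9 against 10 samples gave p under 0.05 in 4.5%, 57.5% and 98.5% of draws for shifts of 0, 1 and 2 SD. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for the remaining steps. Sequences and functions inferred from them were not analysed here.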

Results

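The bacteria of the stomach were profiled in 36 samples from male C57BL/6 mice, an inbred laboratory strain, by sequencing amplicons of the V3 and V4 regions of the 16S rRNA gene, which serves to identify bacteria. The CTL group (n = 10) ate a diet of normal salt content for 4 weeks, and the Salt group (n = 10) ate a diet with 5% NaCl for 4 weeks. The S+B group (n = 9) ate the high-salt diet mixed with buckwheat, a pseudocereal, for 4 weeks. The B group (n = 7) ate the high-salt diet for 4 weeks and buckwheat for the next 4 weeks, so the order and length of feeding differ between B and every other group. Age and time cannot be separated from diet in B, nor buckwheat from the end of the high-salt diet. Total counts per sample lay between 15150 and 38426. Their mean was 28746 ± 2124 (SD) in CTL, 21595 ± 3436 in Salt, 29236 ± 4975 in S+B and 29029 ± 5925 in B. The counts fell in 4106 operational taxonomic units (OTUs, clusters of similar sequences), and 25 of these were annotated as chloroplast or mitochondria and set apart. The remaining 4081 OTUs formed 299 groups at genus level, named by genus or by the lowest rank given, and 34.2% of their counts carried a genus name. S24-7, a family of Bacteroidales common in the rodent gut, held 39.6% of the counts and carried no genus name. Intervals, floors and upper limits cover counting error only. The labels do not state cages or litters, so the p-values measure the spread between these samples.

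**Figure D1:**
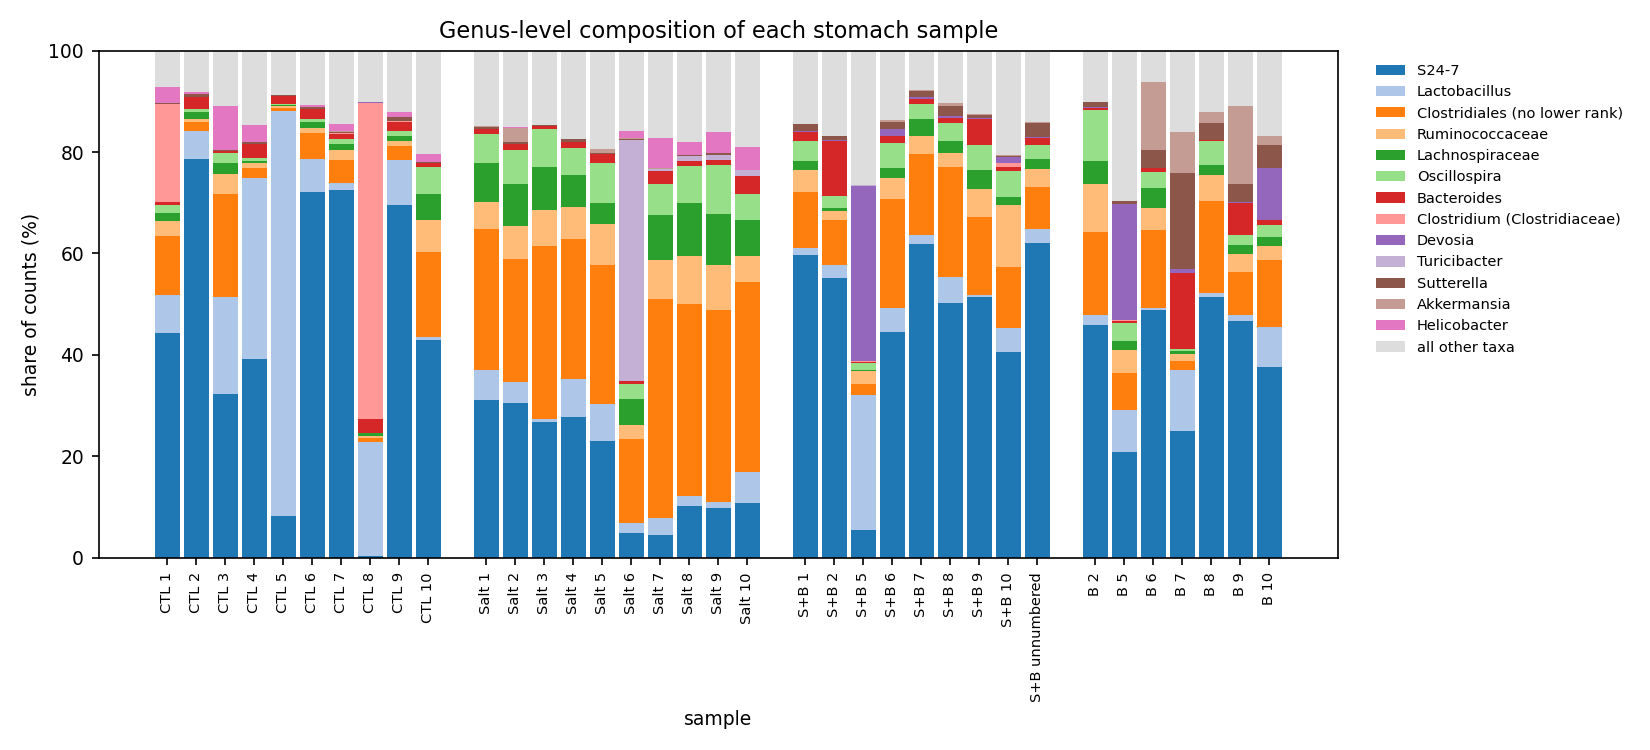
Share of counts (%, stacked bars from 0) of 13 genus-level groups and of all other taxa in each of the 36 samples, ordered by group. S24-7 took 46.0% on average in CTL and 17.9% in Salt, and single samples were dominated by other genera: Lactobacillus in CTL 5, Clostridium in CTL 8, Turicibacter in Salt 6 and Devosia in S+B 5.

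Salt against CTL addressed how a high-salt diet changes the stomach flora. S24-7, whose members ferment complex carbohydrates, took 46.0% ± 27.4 (SD, n = 10) of the counts in CTL and 17.9% ± 10.8 (n = 10) in Salt. Lactobacillus, acid-tolerant lactic acid bacteria that colonise the rodent forestomach, took 18.7% ± 24.1 in CTL and 4.00% ± 2.58 in Salt. Clostridiales without a lower rank, anaerobes of the gut, took 6.59% ± 7.11 in CTL and 31.4% ± 8.06 in Salt. Turicibacter, a spore-forming gut genus, had 4 counts in all of CTL and was found in 10 of 10 Salt samples at 5.08% ± 14.9. Klebsiella, an enterobacterium that can act as an opportunist, took 0.145% ± 0.146 in CTL and had no count in Salt.

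By edgeR's quasi-likelihood test, 29 of 65 genus-level groups changed in Salt, 12 of them higher and 17 lower. Without CTL 5 there were 17 higher and 10 lower, and more were higher than lower as well without CTL 1 or Salt 3, 4, 9 or 10. With library size in place of TMM scaling, 27 changed, 16 higher and 11 lower, because library size raised the fold changes by a median of 1.03 on the log2 scale. Fold changes are given relative to TMM, and no called group turned its sign. Among samples numbered 1 to 5 the count was 22 and among those numbered 6 to 10 it was 12, with 5 samples of each group in each. The calls for Turicibacter, S24-7 and Parabacteroides ended in the first set (3.86, -1.22 and -1.48, adjusted p 0.0703 to 0.152). Those for Lachnospiraceae, Oscillospira, Akkermansia, Lactobacillus and Streptococcus ended in the second (1.64, 1.49, 0.03, -2.50 and -3.59, adjusted p 0.0512 to 1.0), and that for Clostridiales in both. Turicibacter rose by 11.24 ± 1.87 on the log2 scale (SE, adjusted p = 1.85e-05), and all 10 Salt samples lay above the CTL median. Salt 6 carried most of it: without that sample the Salt mean was 0.377% ± 0.457 (n = 9) and the log2 change 6.62 (adjusted p = 6.61e-05). Rikenellaceae, gut Bacteroidales, rose by 3.02 ± 0.69 (adjusted p = 0.000566), and YS2, an order placed among the Cyanobacteria, rose by 3.45 ± 0.75 (adjusted p = 0.00034), each in 10 of 10 samples. Lachnospiraceae rose by 1.37 ± 0.44 (adjusted p = 0.0115) and Oscillospira by 1.28 ± 0.46 (adjusted p = 0.0233), each in 10 of 10 samples; without CTL 1 the changes were 2.07 and 1.98. Clostridiales without a lower rank rose by 1.22 ± 0.46 (adjusted p = 0.0304, 10 of 10 samples). That call ended without CTL 2, CTL 4, CTL 7 or CTL 9 (adjusted p 0.0514 to 0.0617) and in a fit of the 2 groups alone (adjusted p = 0.108). The change was 1.89 without CTL 1 or CTL 5 and 1.86 without Salt 10. Akkermansia, a mucin degrader, rose by 2.75 ± 1.07 (adjusted p = 0.0347, 9 of 10 samples). That call ended without CTL 2, CTL 4, CTL 8 or Salt 8 (adjusted p 0.0527 to 0.0556) and without Salt 2 (1.42, adjusted p = 0.264). It was not made on the centred log ratio (2.12, adjusted p = 0.126).

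S24-7 fell by 2.64 ± 0.54 on the log2 scale in Salt (adjusted p = 0.000162, 10 of 10 samples below the CTL median), and by 1.70 without CTL 5 (adjusted p = 0.0111). The call was not made on the centred log ratio with limma (adjusted p = 0.126). Lactobacillus fell by 3.62 ± 0.86 (adjusted p = 0.000674, 10 of 10 samples). It took 79.7% of the counts of CTL 5 (95% Wilson interval 79.3% to 80.2%), and without that sample the CTL mean was 11.9% ± 11.6 (n = 9) and the call ended (adjusted p = 0.0856). It also ended on the centred log ratio with group and number set as a random block (adjusted p = 0.0525). Clostridium of the Clostridiaceae fell (adjusted p = 2.76e-05, 10 of 10 samples), from 8.21% ± 19.96 to 0.0130% ± 0.00768; CTL 8 held 62.4% (Wilson interval 61.8% to 62.9%), and the CTL mean without it was 2.19% ± 6.41 (n = 9). Klebsiella was at least 103-fold lower in Salt (floor of 3 counts over the group, adjusted p = 1.23e-05), and AF12, a genus of the Rikenellaceae, at least 75.5-fold lower (adjusted p = 6.29e-05), with all 10 Salt samples at 0. Faecalibacterium, a butyrate producer, fell by 6.40 ± 1.18 (adjusted p = 0.000162), Enterobacteriaceae without a genus by 5.33 ± 1.27 (adjusted p = 0.000674), Erwinia by 5.67 ± 1.12 (adjusted p = 0.000162) and Streptococcus by 4.27 ± 0.97 (adjusted p = 0.000549), each in 10 of 10 samples. Parabacteroides, another gut Bacteroidales, fell by 3.15 ± 0.82 (adjusted p = 0.00157, 10 of 10 samples), a call that ended without CTL 5 (-1.87, adjusted p = 0.0829) or Salt 9 (-2.07, adjusted p = 0.0545), and with library size (-1.67, adjusted p = 0.0783). Calls for lower Ruminococcus of the Lachnospiraceae, Desulfovibrio and Devosia (adjusted p = 0.00671, 0.0475 and 0.0274) were the least stable. They ended without any 1 of 11 samples (CTL 1, 5, 7, 8 and 10, Salt 3, 4, 6, 8, 9 and 10; -1.01 at the least), of 18 samples (each except CTL 2 and Salt 9; -2.11 at the least) and of 7 samples (CTL 1, 5, 7 and 8, Salt 3, 4 and 9). All 3 also ended with library size, with no filter on low counts, with organelle OTUs kept and without the unnumbered S+B sample (adjusted p 0.0524 to 0.282), and without CTL 8, Salt 6, S+B 5 and B 5 together (adjusted p 0.0687 to 1.0). DESeq2 ended those of Desulfovibrio and Devosia (adjusted p = 0.161 and 0.0641), and a fit of the 2 groups alone that of Desulfovibrio (adjusted p = 0.21). The centred log ratio ended those of Ruminococcus and Devosia (adjusted p = 0.404 and 0.633). Devosia's 22 counts in CTL were all in CTL 8. Ruminococcaceae without a genus (2.05% ± 1.92 in CTL and 6.71% ± 2.02 in Salt, adjusted p = 0.184) passed with DESeq2, library size or the centred log ratio (adjusted p = 0.0106, 0.00225 and 0.00548). It also passed without the unnumbered S+B sample (adjusted p = 0.0364) and without CTL 1, 5, 8 or 10 or Salt 3, 6 or 10 (adjusted p 0.0128 to 0.0495). Bacteroides, a major polysaccharide degrader of the gut, at 1.56% ± 0.870 and 1.48% ± 0.976 (adjusted p = 0.0604), passed without CTL 3 (adjusted p = 0.0411) and in a fit of the 2 groups alone (adjusted p = 0.047). Prevotella of the Paraprevotellaceae stood at 0.553% ± 0.684 and 0.869% ± 0.660 (adjusted p = 0.502).

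Of the 9 taxon lists, 2 changed in Salt by a permutation test on log2 shares. Enterobacteria and other opportunist Gammaproteobacteria fell from 0.266% ± 0.259 to 0.0204% ± 0.0330 (adjusted p = 0.00432), and Klebsiella was the 1 of 2 tested genera that fell, also when adjusted over the list alone. Clostridia that produce butyrate and other short-chain fatty acids rose from 3.86% ± 3.47 to 10.4% ± 3.12 (adjusted p = 0.00432); of 7 tested genera, Oscillospira rose and Faecalibacterium and Ruminococcus fell, the same counts when adjusted over the list alone. Both lactic acid genera tested fell, also when adjusted over the list alone, but the list's share did not pass (18.9% ± 24.1 and 4.03% ± 2.60, adjusted p = 0.147). Gut Bacteroidales stood at 48.9% ± 27.8 and 21.9% ± 12.1 (adjusted p = 0.148), with 2 of 6 tested members lower, also over the list alone. The list passed on the percent scale (adjusted p = 0.0487) and without 4 set-aside samples (adjusted p = 0.0346). These were CTL 8, Salt 6, S+B 5 and B 5, chosen for their shares of Clostridium, Turicibacter and Devosia, and CTL 5 with its Lactobacillus stayed in. Helicobacter and relatives, spiral bacteria that colonise the gastric mucus, stood at 2.00% ± 2.61 and 1.91% ± 2.37 (adjusted p = 0.39), and neither member changed. Genera that respond to fibre and mucin stood at 2.77% ± 1.59 and 7.02% ± 14.8 (adjusted p = 0.87), with Turicibacter and Akkermansia higher and Desulfovibrio lower among 5, also over the list alone. Salt-tolerant and skin or bedding bacteria, a list of Gram-positives that also holds the Gram-negative Halomonas, did not pass (0.0418% ± 0.0252 and 0.112% ± 0.168, adjusted p = 0.621), nor did genera common as contaminants of DNA kits or water (0.179% ± 0.170 and 0.261% ± 0.513, adjusted p = 0.906) or plant organelle DNA (0.0793% ± 0.130 and 0.203% ± 0.547, adjusted p = 0.789). Single samples moved several of these means. Without Salt 6 the Salt means were 2.38% ± 1.70 for fibre and mucin genera, 0.101% ± 0.101 for kit and water genera and 0.0107% ± 0.0126 for enterobacteria (n = 9). Without CTL 5 lactic acid bacteria averaged 12.1% ± 11.6 in CTL and organelle DNA 0.0457% ± 0.0792, and without CTL 3 Helicobacter and relatives averaged 1.27% ± 1.25. In Salt, organelle DNA averaged 0.0297% ± 0.0336 without Salt 4 and salt-tolerant bacteria 0.0638% ± 0.0794 without Salt 5. Neither of the tested members changed in the salt-tolerant list or in the contaminant list, and no organelle group was tested singly.

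At the phylum level, Firmicutes rose from 42.0% ± 27.7 in CTL to 66.5% ± 8.41 in Salt (permutation test, adjusted p = 0.0334), and Bacteroidetes fell from 49.5% ± 28.0 to 26.8% ± 11.3 (adjusted p = 0.0453). The Bacteroidetes call was not made on the log2 scale (adjusted p = 0.268) or on ranks (adjusted p = 0.0536). Verrucomicrobia rose from 0.0424% ± 0.0529 to 0.460% ± 0.898 (adjusted p = 0.0453), but not without the 4 set-aside samples (adjusted p = 0.105). The Salt mean was 0.185% ± 0.244 (n = 9) without Salt 2, and the CTL mean 0.0277% ± 0.0267 (n = 9) without CTL 7. Proteobacteria stood at 7.03% ± 3.03 and 4.14% ± 3.36 (adjusted p = 0.0764), with a call on the log2 scale (adjusted p = 0.0489) and without the 4 set-aside samples (adjusted p = 0.0219). The log2 ratio of Firmicutes to Bacteroidetes was -0.15 ± 2.37 in CTL and 1.45 ± 0.91 in Salt (adjusted p = 0.0764), with a call on ranks (adjusted p = 0.0434) and without those 4 samples (adjusted p = 0.0193). Salt samples held more OTUs at equal depth, 808.8 ± 98.3 against 504.7 ± 108 (permutation p = 2e-05, the smallest that the resamples can give; adjusted p = 0.00024), and a higher Shannon index, 4.82 ± 0.60 against 3.49 ± 0.73 (adjusted p = 0.00252).

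**Figure D2:**
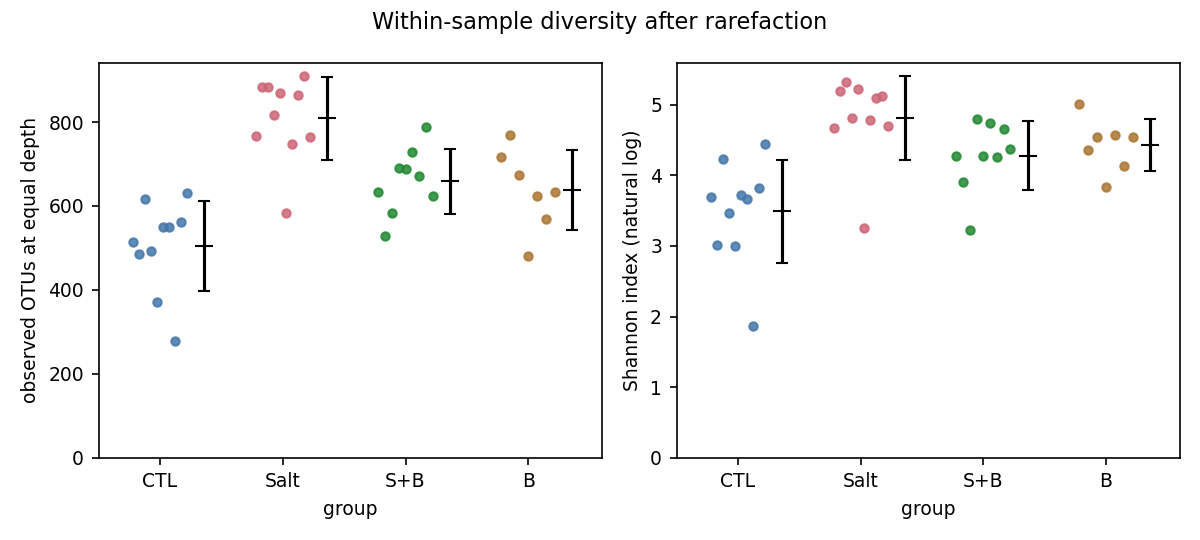
Observed OTUs at equal depth (left) and Shannon index (right) of each sample by group, with points for samples and bars for mean and SD. Salt had the highest mean of both measures (808.8 OTUs and 4.82) and CTL the lowest (504.7 OTUs and 3.49).

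Of 374 OTUs tested, 209 differed between Salt and CTL, 130 higher and 79 lower (178 and 43 with library size). OTU173 and OTU2990, both S24-7, took 5.69% ± 3.10 and 3.95% ± 3.31 in CTL and had no count in Salt. They were at least 4110-fold and 2830-fold lower (adjusted p = 1.99e-07 each, 10 of 10 samples). OTU852, also S24-7, stood 225-fold lower (95% counting interval 76.8 to 1090) on 3 counts in Salt (adjusted p = 1.99e-07). OTU890, also S24-7, took 0.296% ± 0.264 in Salt, at least 276-fold higher (adjusted p = 4.25e-07, 9 of 10 samples). OTU4054, a Bifidobacterium, took 0.865% ± 0.349 in Salt and had 2 counts in CTL, a ratio of 1210 (counting interval 336 to 10000, adjusted p = 1.99e-07, 10 of 10 samples). Its genus took 0.0551% to 1.44% in CTL, and its other 2 tested OTUs fell. OTU1098, a Clostridiales, rose by 6.70 ± 0.95 to 5.37% ± 4.71 (adjusted p = 5.73e-07, counts in 10 of 10 samples).

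S+B against Salt addressed what buckwheat given together with salt changes. S24-7 took 47.9% ± 17.6 (n = 9) in S+B against 17.9% ± 10.8 (n = 10) in Salt. Helicobacter, the genus that includes gastric pathogens, took 1.81% ± 2.24 in Salt and had 3 counts in S+B, a ratio of 1520 (95% counting interval 519 to 7370). Devosia, a soil and water genus, had no count in Salt and took 4.27% ± 11.4 in S+B, and Halomonas, a salt-loving genus, also had none in Salt and took 0.860% ± 2.27. Both were present in 9 of 9 S+B samples. Allobaculum, a rodent gut genus of the Erysipelotrichaceae, took 0.981% ± 0.992 in S+B and 0.0201% ± 0.0364 in Salt.

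**Figure D3:**
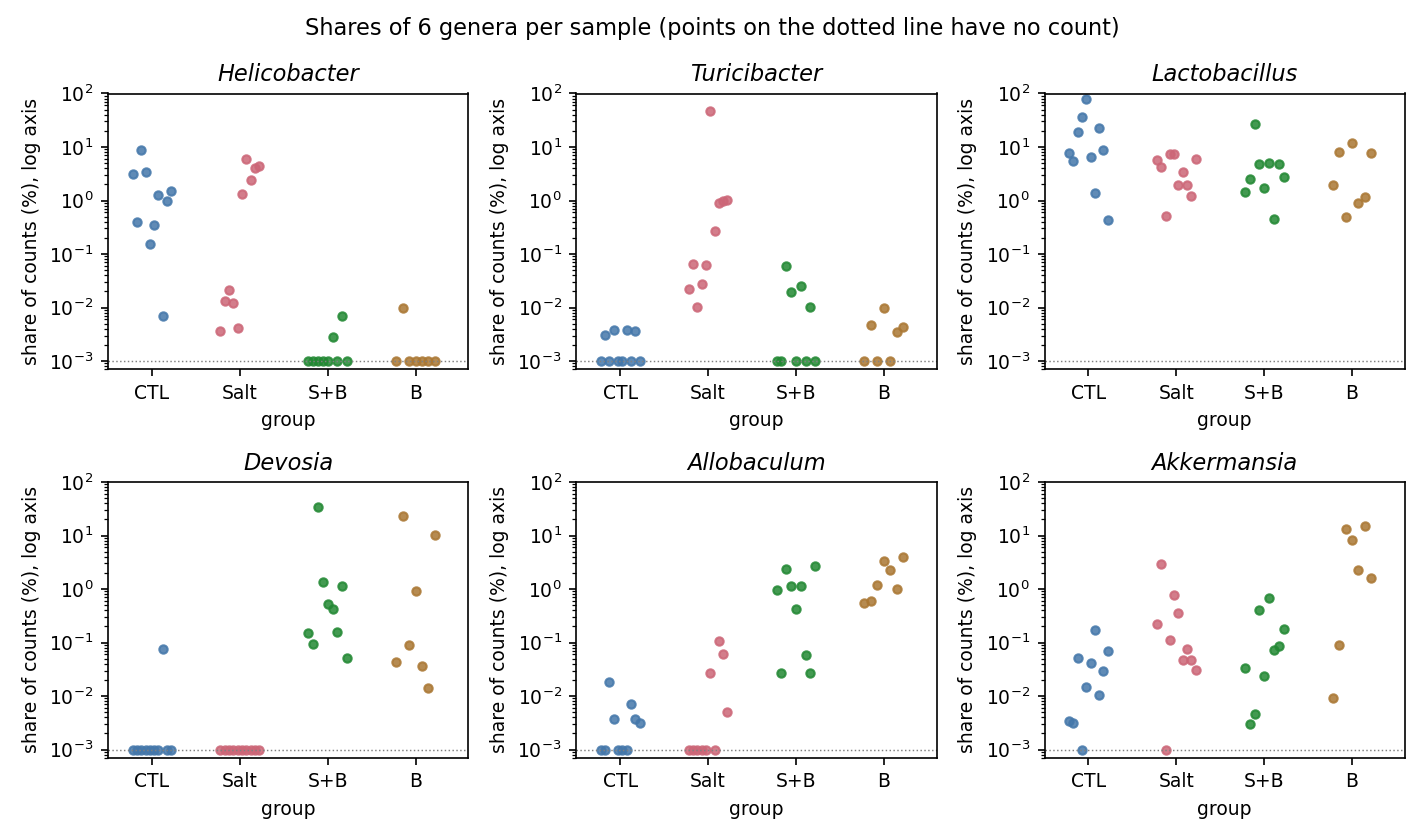
Share of counts (%, log axis) of 6 genera in each sample by group; each point is a sample, and points on the dotted line had no count. Helicobacter counts were found in 2 of 9 S+B and 1 of 7 B samples, and Devosia counts in all S+B and B samples and in 1 of 20 CTL and Salt samples.

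In S+B, 29 of 65 genus-level groups changed against Salt, 18 higher and 11 lower by edgeR. Without S+B 5 there were 12 higher and 15 lower, and without Salt 10 there were 14 and 15. With library size 28 changed, 14 higher and 14 lower, on a median shift of -0.59 that turned no called sign. The count was 26 among samples numbered 6 to 10 and 1, Allobaculum, among those numbered 1 to 5, where 3 S+B samples stood against 5 of Salt and 21 groups had an unadjusted p under 0.05. Every other call named here ended there. Devosia, Halomonas and Aminobacter, an aerobic genus of soil and water, were at least 2420-fold, 488-fold and 237-fold higher in S+B (adjusted p = 9.47e-05, 0.000667 and 0.00148; 9 of 9 samples each). Without S+B 5, in which Devosia reached 34.5% (Wilson interval 33.9% to 35.2%), the bounds were 350.0-fold, 74.7-fold and 32.3-fold and the means of Devosia and Halomonas 0.487% ± 0.50 and 0.104% ± 0.109 (n = 8). Allobaculum rose by 6.75 ± 1.22 (adjusted p = 8.29e-05, 9 of 9 samples), Coprobacillus by 5.77 ± 1.42 (adjusted p = 0.00151, 7 of 9), RF32, an order of Alphaproteobacteria, by 3.36 ± 0.87 (adjusted p = 0.00229, 9 of 9) and Anaerostipes, a butyrate producer, by 3.71 ± 1.06 (adjusted p = 0.00477, 6 of 9). Coprobacillus stood at 0.106% ± 0.161, and at 0.0677% ± 0.119 (n = 8) without S+B 2. Prevotella of the Paraprevotellaceae rose by 2.72 ± 0.66 (adjusted p = 0.00148, 8 of 9) and S24-7 by 2.01 ± 0.53 (adjusted p = 0.00261, 8 of 9), or 1.32 without Salt 10 (adjusted p = 0.0483). Parabacteroides rose by 2.57 ± 0.81 (adjusted p = 0.00846, 8 of 9), but not without Salt 8 (2.10, adjusted p = 0.0584) or Salt 10 (1.91, adjusted p = 0.0646). Calls for higher Rhizobiales, Phyllobacteriaceae, Clostridium, Staphylococcus and Streptococcus (adjusted p 0.0171 to 0.0494) depended on single samples. Rhizobiales and Phyllobacteriaceae turned to -0.54 and -0.90 without S+B 5. The Rhizobiales call also ended without Salt 8 or Salt 10 (adjusted p 0.051 to 0.0523). The Phyllobacteriaceae call ended without any Salt sample except Salt 6 (5.93 without that sample) and without S+B 7, 9 or 10 (adjusted p 0.0587 to 0.0986). Clostridium ended without Salt 1, 2, 3, 4, 5, 7 or 9 or S+B 5, 7 or 10 (adjusted p 0.0526 to 0.232; 2.05 without S+B 10). Staphylococcus ended without Salt 1, 2, 3, 4, 7, 8, 9 or 10 or S+B 2, 5, 7, 9 or 10 (adjusted p 0.0537 to 0.209; 1.63 without Salt 8 or Salt 10, 1.80 without S+B 5 and 1.87 without S+B 2). Streptococcus ended without Salt 1, 2, 3, 4, 5, 7 or 9 or S+B 5, 7, 9 or 10 (adjusted p 0.06 to 0.411; 0.98 without S+B 10). All 5 calls also ended with no filter on low counts, on the centred log ratio and without CTL 8, Salt 6, S+B 5 and B 5 (adjusted p 0.0523 to 0.784). All but that of Rhizobiales ended with library size (adjusted p 0.0551 to 0.217). Those of Phyllobacteriaceae, Staphylococcus and Streptococcus ended with organelle OTUs kept, in a fit of the 2 groups alone and without the unnumbered S+B sample (adjusted p 0.0502 to 0.0745). That of Clostridium ended with DESeq2 (adjusted p = 0.0976), and all but Staphylococcus with the number set as a block (adjusted p 0.0579 to 0.348). With group and number set as a random block on the centred log ratio, S24-7 did not pass (adjusted p = 0.0589).

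Helicobacter was the deepest fall in S+B (log2 change -9.79 ± 1.58, adjusted p = 1.93e-05), with 9 of 9 samples below the Salt median. Its level in Salt was uneven: 0.0108% ± 0.00711 in samples 1 to 5 and 3.61% ± 1.80 in samples 6 to 10 (n = 5 each). All of Salt 1 to 5, fed no buckwheat, lay below the Salt median as well. Flexispira, a relative, fell by 5.17 ± 1.35 (adjusted p = 0.00229, 9 of 9), with no count in Salt 1 to 5 and 204 counts in Salt 6 to 10. Turicibacter fell by 8.41 ± 1.73 (adjusted p = 0.000335, 9 of 9) to 0.0126% ± 0.0199, or by 3.81 without Salt 6 (adjusted p = 0.00487). Bifidobacterium, a carbohydrate fermenter, fell by 3.64 ± 0.91 (adjusted p = 0.0016, 9 of 9) from 0.948% ± 0.413 to 0.0507% ± 0.0502. Lachnospiraceae fell by 1.49 ± 0.46 (adjusted p = 0.00846, 9 of 9) and F16, a family of the candidate phylum TM7, by 2.46 ± 0.80 (adjusted p = 0.0113, 9 of 9). Both calls ended among samples 6 to 10 as well, where Salt and S+B had 5 samples each, and that of Lachnospiraceae with no filter (adjusted p = 0.106). Faecalibacterium had no count in S+B and was at least 13.7-fold lower (adjusted p = 0.00477, but 0.0589 with the random block), with 4 of 10 Salt samples above 0. Desulfovibrio, a sulfate reducer, fell by 4.31 ± 1.46 (adjusted p = 0.015) on counts in 4 of 10 Salt samples. Its call ended among samples 6 to 10, with the number set as a block (adjusted p = 0.0781), with no filter (adjusted p = 0.0608) and on the centred log ratio (adjusted p = 0.18). Rikenellaceae fell by 2.23 ± 0.70 (adjusted p = 0.00846, 9 of 9), but not without Salt 6 (-1.64, adjusted p = 0.0799) or S+B 6 (-1.62, adjusted p = 0.0908). Stenotrophomonas, a genus of water and soil, fell by 4.22 ± 1.31 (adjusted p = 0.00846, 8 of 9), by 2.30 without Salt 6 (adjusted p = 0.0749) and by 7.23 without S+B 5. Clostridiales without a lower rank (13.0% ± 6.35 in S+B, adjusted p = 0.176) passed without Salt 10 (adjusted p = 0.0483), with library size (adjusted p = 0.0441) and in a fit of the 2 groups alone (adjusted p = 0.0345). Lactobacillus (5.58% ± 8.07, or 2.94% ± 1.75 without S+B 5, adjusted p = 0.0672) passed without S+B 1 (adjusted p = 0.0493) and with DESeq2 (adjusted p = 0.0465). Bacteroides (2.63% ± 3.43, or 1.59% ± 1.51 without S+B 2, adjusted p = 0.0741) passed without Salt 6 or S+B 6 (adjusted p 0.0277 to 0.0426). Oscillospira (3.56% ± 1.33, adjusted p = 0.725) and Ruminococcaceae (4.56% ± 3.15, adjusted p = 1.0) did not pass.

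Among the lists, Helicobacter and relatives fell from 1.91% ± 2.37 in Salt to 0.00293% ± 0.00782 in S+B (exact permutation test, adjusted p = 0.00789), and both members fell, also over the list alone. Gut Bacteroidales rose from 21.9% ± 12.1 to 56.1% ± 20.5 (exact permutation test, adjusted p = 0.0358), with S24-7, Parabacteroides and Prevotella higher among 6, also over the list alone. Short-chain fatty acid producers fell from 10.4% ± 3.12 to 6.29% ± 3.36 (exact permutation test, adjusted p = 0.039, or 0.0514 on the percent scale), while Anaerostipes rose and Faecalibacterium fell among 7. The other lists did not pass in exact permutation tests. Lactic acid bacteria stood at 5.64% ± 8.09 (adjusted p = 0.977), fibre and mucin genera at 1.23% ± 1.08 (adjusted p = 0.0894), salt-tolerant and skin or bedding bacteria at 0.974% ± 2.36 (adjusted p = 0.159) and enterobacteria at 0.0686% ± 0.0976 (adjusted p = 0.284). Kit and water genera stood at 0.0850% ± 0.211 (adjusted p = 0.104, or 0.00407 without the 4 set-aside samples) and plant organelle DNA at 0.670% ± 0.751 (adjusted p = 0.0578). Without S+B 5 the S+B means were 3.01% ± 1.82 for lactic acid bacteria, 0.188% ± 0.169 for salt-tolerant bacteria, 0.0424% ± 0.0622 for enterobacteria and 0.0148% for kit and water genera (n = 8). Without S+B 10 Helicobacter and relatives averaged 0.000346%. Among their tested members, Allobaculum rose and Turicibacter, Bifidobacterium and Desulfovibrio fell in the fibre and mucin list, Halomonas and Staphylococcus rose in the salt-tolerant list, Streptococcus rose in the lactic acid list (both members over the list alone), and Stenotrophomonas fell in the kit and water list. No enterobacterial member changed (both rose over the list alone). Bacteroidetes rose to 57.3% ± 20.9 (exact permutation test, adjusted p = 0.00448) and Firmicutes fell to 33.4% ± 9.25 (adjusted p = 0.000325), and the log2 ratio of Firmicutes to Bacteroidetes fell to -0.63 ± 1.26 (adjusted p = 0.00438). Proteobacteria at 8.23% ± 16.5 (adjusted p = 0.818) and Verrucomicrobia at 0.165% ± 0.230 (adjusted p = 0.481) did not pass. Proteobacteria averaged 2.74% ± 0.762 (n = 8) without S+B 5, below Salt, and Verrucomicrobia 0.102% ± 0.138 without S+B 8. S+B samples held fewer OTUs than Salt (659.3 ± 77.5, exact permutation test, adjusted p = 0.00717), while the Shannon index of 4.28 ± 0.48 did not pass (adjusted p = 0.067, or 0.00296 without the 4 set-aside samples). Without rarefaction the OTU count differed by -80.8, which did not pass (exact permutation test, adjusted p = 0.189).

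At the OTU level, 152 of 374 changed in S+B against Salt, 70 higher and 82 lower (45 higher and 103 lower with library size). OTU1846 of S24-7 alone took 12.1% ± 8.96 in S+B and 0.0323% ± 0.0842 in Salt, a rise of 9.43 ± 1.41 (adjusted p = 9.8e-06), with counts in 9 of 9 S+B and 4 of 10 Salt samples. OTU3134 and OTU1866, both S24-7, rose by 7.12 ± 1.03 (adjusted p = 6.28e-06) and 3.80 ± 0.61 (adjusted p = 9.8e-06) with counts in 9 of 9 samples each. OTU640, a Clostridiales, fell by 8.24 ± 1.15 (adjusted p = 3.66e-06) from 2.36% ± 2.29. OTU1633, also Clostridiales, had 3 counts in S+B, a ratio of 654 (counting interval 223 to 3180, adjusted p = 1.86e-06), and OTU715 of the Rikenellaceae 1 count, a ratio of 314 (counting interval 55.9 to 12500.0, adjusted p = 6.28e-06).

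B against Salt addressed what buckwheat changes when it follows the high-salt diet. Its differences also cover the 4 further weeks of feeding and the end of the high-salt diet. No group left that diet without buckwheat, so these cannot be told apart. Akkermansia took 5.84% ± 6.46 (n = 7) of the counts in B and 0.459% ± 0.899 (n = 10) in Salt. Sutterella, a betaproteobacterium of the gut, took 5.05% ± 6.23 in B and 0.250% ± 0.118 in Salt. S24-7 took 39.5% ± 12.1 in B. Helicobacter had 2 counts in B, a ratio of 1760 (95% counting interval 487 to 14600), and Desulfovibrio 1 count, a ratio of 1000 (counting interval 179 to 39600). Devosia took 4.91% ± 8.83 and Halomonas 1.18% ± 2.16 in B, each with counts in 7 of 7 samples.

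In B, 27 of 65 genus-level groups changed against Salt, 13 higher and 14 lower by edgeR. Without B 7 there were 8 higher and 19 lower. With library size 28 changed, 11 higher and 17 lower, on a median shift of -0.40 that turned no called sign. The count was 28 among samples numbered 6 to 10 and 1, Allobaculum, among those numbered 1 to 5, where B had 2 samples and 13 groups had an unadjusted p under 0.05. Every other call named here ended there. Devosia, Halomonas and Aminobacter were at least 2650-fold, 636-fold and 219-fold higher in B (adjusted p = 9.19e-05, 0.000976 and 0.00216; 7, 7 and 5 of 7 samples). Without B 5, in which Devosia reached 23.0% (Wilson interval 22.5% to 23.6%), the bounds were 1360-fold, 310.0-fold and 99.8-fold and the means of Devosia and Halomonas 1.89% ± 4.10 and 0.432% ± 0.935 (n = 6). Allobaculum rose by 6.86 ± 1.24 (adjusted p = 7.39e-05) and Butyricimonas, a butyrate producer of the Bacteroidales, by 3.78 ± 0.73 (adjusted p = 9.19e-05), each in 7 of 7 samples. Sutterella rose by 4.50 ± 0.67 (adjusted p = 4.06e-06, 7 of 7), or 2.88 without B 7 (adjusted p = 0.000772), where the mean was 2.76% ± 1.62 (n = 6). Akkermansia rose by 4.21 ± 1.17 (adjusted p = 0.00343, 5 of 7). It stood at 0.0505% ± 0.0584 in B 2 and B 5 and at 8.15% ± 6.25 in B 6 to 10 (n = 5), and with the number set as a block its call ended (3.27, adjusted p = 0.0611). Coprobacillus rose by 5.40 ± 1.43 (adjusted p = 0.00216, 4 of 7), RF32 by 3.76 ± 0.91 (adjusted p = 0.00138, 6 of 7) and Parabacteroides by 3.23 ± 0.85 (adjusted p = 0.00216, 4 of 7), but none of the 3 without B 7 (3.02, 1.99 and 0.90, adjusted p = 0.0723, 0.0531 and 0.399). The Coprobacillus call was not made on the centred log ratio (adjusted p = 0.0606), and that of Parabacteroides ended there with the random block (adjusted p = 0.0508). Parabacteroides changed by 4.92 without B 2 and 4.93 without B 8. S24-7 rose by 1.69 ± 0.55 (adjusted p = 0.0119, 7 of 7), but not without Salt 8, Salt 10, B 7 or B 10 (0.69 to 0.79, adjusted p 0.316 to 0.392), with library size (1.14, adjusted p = 0.088) or on the centred log ratio (adjusted p = 0.0595).

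Helicobacter fell by 9.61 ± 1.77 on the log2 scale in B (adjusted p = 7.39e-05) and Flexispira fell by 6.12 ± 1.62 (adjusted p = 0.00216), each in 7 of 7 samples below the Salt median. Salt 1 to 5, fed no buckwheat, also lay below it, with 11 Helicobacter counts and no Flexispira count. Turicibacter fell by 11.04 ± 2.16 (adjusted p = 9.19e-05, 7 of 7), or by 5.67 without Salt 6 (adjusted p = 0.00109). Ochrobactrum, an environmental genus of the Brucellaceae, had no count in B and was at least 462-fold lower (adjusted p = 9.19e-05, 7 of 7), or 145-fold without Salt 6. Desulfovibrio fell by 8.40 ± 2.07 (adjusted p = 0.00153), on counts in 4 of 10 Salt samples, and the call was not made on the centred log ratio (adjusted p = 0.0574). Bifidobacterium fell by 3.74 ± 1.01 (adjusted p = 0.00262), F16 by 3.72 ± 0.95 (adjusted p = 0.00216) and YS2 by 3.23 ± 0.85 (adjusted p = 0.00216; -4.88 without B 7), each in 7 of 7 samples. Stenotrophomonas fell by 5.37 ± 1.51 (adjusted p = 0.00363, 7 of 7), or by 3.0 without Salt 6 (adjusted p = 0.038), and Faecalibacterium was at least 10.6-fold lower (adjusted p = 0.00881, but 0.111 on the centred log ratio). Prevotellaceae fell by 4.06 ± 1.36 (adjusted p = 0.0132, 6 of 7), but not without Salt 4 (-3.21, adjusted p = 0.0513), on the centred log ratio (adjusted p = 0.147) or with the number set as a block (-2.34, adjusted p = 0.219). Rikenellaceae fell by 2.14 ± 0.77 (adjusted p = 0.021, 7 of 7), but not without Salt 3, 4, 6 or 9 or B 2, 5, 6, 8 or 9 (adjusted p 0.0629 to 0.187). That call also ended with no filter, with organelle OTUs kept, on the centred log ratio and without the 4 set-aside samples or the unnumbered S+B sample (adjusted p 0.0625 to 0.0905). Lachnospiraceae (2.30% ± 1.39 in B, adjusted p = 0.0519) passed without Salt 5, 8 or 10 or B 6, 7 or 10 (adjusted p 0.00228 to 0.039) and Clostridiales (11.6% ± 5.86, adjusted p = 0.184) without Salt 8, Salt 10, B 7 or B 10 (adjusted p 0.00647 to 0.0156). Both passed with library size (adjusted p = 0.00804 and 0.0371) and in a fit of the 2 groups alone (adjusted p = 0.013 and 0.0432). Lachnospiraceae also passed with DESeq2 (adjusted p = 0.0215) and with the number set as a block (adjusted p = 0.0467). Bacteroides (3.42% ± 5.51, or 1.51% ± 2.39 without B 7, adjusted p = 0.139) passed with DESeq2, with no filter, with organelle OTUs kept and in a fit of the 2 groups alone (adjusted p 0.00767 to 0.0265). It also passed without the unnumbered S+B sample or the 4 set-aside samples (adjusted p 0.0023 to 0.00595) and without Salt 3, 4, 6 or 9 or B 2, 5, 6 or 8 (adjusted p 0.00246 to 0.0224). Prevotella of the Paraprevotellaceae (1.51% ± 1.30, adjusted p = 0.129) passed without B 5 (adjusted p = 0.0281), without the 4 set-aside samples, in a fit of the 2 groups alone and with the number set as a block (adjusted p 0.0203 to 0.0468). Lactobacillus (4.66% ± 4.64, adjusted p = 0.713), Clostridium (0.0287% ± 0.0497, adjusted p = 0.394), Oscillospira (3.79% ± 3.13, adjusted p = 0.795) and Ruminococcaceae (4.44% ± 2.49, adjusted p = 1.0) did not pass.

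Helicobacter and relatives fell as a list to 0.00207% ± 0.00548 in B (exact permutation test, adjusted p = 0.00789), and both members fell, also over the list alone. Gut Bacteroidales rose to 45.5% ± 11.4 (exact permutation test, adjusted p = 0.0172), with S24-7 and Parabacteroides higher among 6, also over the list alone. Plant organelle DNA rose to 0.586% ± 0.486 (exact permutation test, adjusted p = 0.0369), but not on the percent scale (adjusted p = 0.303), with 0.1 added before the log (adjusted p = 0.071) or without the 4 set-aside samples (adjusted p = 0.0575). The other lists did not pass in exact permutation tests. Short-chain fatty acid producers stood at 6.06% ± 4.30 (adjusted p = 0.0578, or 0.0291 without the 4 set-aside samples) and kit and water genera at 0.0415% ± 0.0775 (adjusted p = 0.0578, or 0.0135 without them). Fibre and mucin genera stood at 7.72% ± 6.48 (adjusted p = 0.553), salt-tolerant and skin or bedding bacteria at 1.65% ± 3.16 (adjusted p = 0.183), lactic acid bacteria at 4.69% ± 4.67 (adjusted p = 0.831) and enterobacteria at 0.0664% ± 0.102 (adjusted p = 0.326). Without B 5 the B means were 0.503% ± 0.956 for salt-tolerant bacteria, 0.0292% ± 0.0297 for enterobacteria and 0.0138% ± 0.0278 for kit and water genera (n = 6), and no count of Helicobacter and relatives was left. Among their tested members, Allobaculum and Akkermansia rose and Turicibacter, Bifidobacterium and Desulfovibrio fell in the fibre and mucin list, Halomonas rose in the salt-tolerant list, Faecalibacterium fell in the short-chain fatty acid list and Stenotrophomonas in the kit and water list (both members over the list alone). Neither lactic acid nor enterobacterial members changed. Firmicutes fell to 32.9% ± 8.82 (exact permutation test, adjusted p = 0.000771), Bacteroidetes rose to 46.6% ± 11.7 (adjusted p = 0.00977) and their log2 ratio fell to -0.50 ± 0.63 (adjusted p = 0.00103). Verrucomicrobia rose to 5.84% ± 6.46 (exact permutation test, adjusted p = 0.0334), but not on the log2 scale (adjusted p = 0.0602) or on ranks (adjusted p = 0.0878), and Proteobacteria at 13.1% ± 13.0 did not pass (adjusted p = 0.0764). B samples held 637.8 ± 94.5 OTUs (exact permutation test, adjusted p = 0.00905 at equal depth and 0.0873 without rarefaction) and a Shannon index of 4.43 ± 0.37 (adjusted p = 0.189, or 0.0107 without the 4 set-aside samples).

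Of single OTUs, 147 of 374 changed in B against Salt, 66 higher and 81 lower (45 higher and 91 lower with library size). OTU1497, a Sutterella, rose by 8.70 ± 1.06 to 4.20% ± 5.63 (adjusted p = 9.47e-08), OTU581 of the Ruminococcaceae by 8.38 ± 1.27 (adjusted p = 4.92e-06) and OTU2495, a Ruminococcus, by 5.69 ± 0.91 (adjusted p = 1.18e-05), each with counts in 7 of 7 B samples. OTU640 and OTU1633 of the Clostridiales had no count in B and were at least 1550-fold and 506-fold lower (adjusted p = 7.26e-07 for each). OTU3785 of the Lachnospiraceae had 1 count, a ratio of 113 (counting interval 20 to 4520, adjusted p = 1.43e-05).

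Against CTL, the buckwheat groups kept Helicobacter near its floor: 1.98% ± 2.61 in CTL against 3 counts in S+B (a ratio of 1680, counting interval 574 to 8140, adjusted p = 1.41e-06) and 2 in B (1950, counting interval 539 to 16100, adjusted p = 1.44e-05). Without CTL 3 the CTL mean was 1.24% ± 1.25 (n = 9). Faecalibacterium had no count in either group, at least 407-fold and 315-fold lower (adjusted p = 4.58e-06 and 2.12e-05). Allobaculum rose by 7.92 ± 1.31 in S+B (adjusted p = 6.39e-06) and 8.03 ± 1.33 in B (adjusted p = 1.1e-05), in every sample. RF32 had 1 count in CTL, with ratios of 627 in S+B (counting interval 112 to 24800, adjusted p = 1.41e-06) and 1220 in B (counting interval 219 to 48300, adjusted p = 9.41e-07). In all, 32 of 65 groups changed in S+B (15 higher and 17 lower; with library size 37, 21 and 16) and 31 in B (13 and 18; with library size 32, 16 and 16), on median shifts of 0.48 and 0.73. With single samples left out, 11 to 21 were higher and 14 to 18 lower in S+B. In B, 23 were higher and 14 lower without CTL 1, and 20 and 15 without CTL 8. Samples 1 to 5 gave 12 and 10 calls, and samples 6 to 10 gave 25 and 27. Halomonas was at least 650.0-fold higher in S+B and 848-fold in B (adjusted p = 0.00048 and 0.000733), and Aminobacter 315-fold and 291-fold (adjusted p = 0.00111 and 0.0025). Without S+B 5 and B 5 these bounds were 99.6-fold, 414-fold, 43.1-fold and 133-fold. Devosia rose by 9.01 ± 2.08 in S+B (adjusted p = 0.000647; 14.19 without CTL 8 and 5.66 without S+B 5) and by 8.03 ± 2.03 in B (adjusted p = 0.00148; 13.41 without CTL 8). Erwinia stood 310.0-fold lower in S+B on 1 count (counting interval 55.3 to 12300, adjusted p = 1.84e-05), AF12 was at least 91.6-fold lower (adjusted p = 6.59e-05) and Clostridium fell by 7.59 ± 1.75 (adjusted p = 0.000443). In B, Klebsiella and Ochrobactrum were at least 96.1-fold and 420.0-fold lower (adjusted p = 2.47e-05 and 3.27e-05), and Desulfovibrio stood 4080-fold lower on 1 count (counting interval 731 to 161000, adjusted p = 8.06e-05). Among samples 1 to 5, Halomonas, Aminobacter and Devosia passed in neither group, Clostridium did not pass in S+B, and RF32 and Klebsiella did not pass in B (adjusted p 0.0719 to 0.124). Both buckwheat groups held more OTUs than CTL (exact permutation test, adjusted p = 0.00511 in S+B and 0.0218 in B, or 0.0676 in B without the 4 set-aside samples) and a higher Shannon index (adjusted p = 0.0174 and 0.00679).

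B and S+B differed in 3 of 65 genus-level groups by edgeR (8 by DESeq2), with 9 at an unadjusted p under 0.05, none called among samples 1 to 5 (6 at an unadjusted p under 0.05) and 5 among samples 6 to 10. It was also 5 with library size, on the centred log ratio and without the 4 set-aside samples, 5 without B 2, 7 or 8, 6 without B 5 or 6, and 7 without S+B 5 or B 10. Akkermansia was higher in B by 5.37 ± 1.29 (adjusted p = 0.00554, 6 of 7 samples), and S+B held 0.165% ± 0.230 of it, or 0.102% ± 0.138 (n = 8) without S+B 8. YS2 was lower in B by 3.48 on the log2 scale (-3.48 ± 0.87, adjusted p = 0.0057, 7 of 7), but not without S+B 2, 7, 9 or 10 or B 2 or 8 (adjusted p 0.0554 to 0.0921) or among samples 6 to 10 (adjusted p = 0.137). Its call also ended with no filter (adjusted p = 0.107) and without the 4 set-aside samples or the unnumbered S+B sample (adjusted p = 0.0672 and 0.0573). Ochrobactrum, named after its values were seen, was at least 32.0-fold lower in B (adjusted p = 0.00554), or 9.63-fold without S+B 5. Observed OTUs (exact permutation test, adjusted p = 0.627) and the Shannon index (adjusted p = 0.578) did not pass.

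The whole community separated by group. On Bray-Curtis dissimilarity of OTUs, the 4 groups explained 41.9% of the variation (permutation p = 0.0001, the smallest that the permutations can give). The share was 34.6% for Salt against CTL, 29.7% for S+B against Salt, 32.1% for B against Salt, 36.0% for S+B against CTL and 38.3% for B against CTL (permutation tests, adjusted p 0.0002 to 0.00024), and 12.9% for B against S+B (adjusted p = 0.0339). Spread around the group centres did not differ in any pair on this measure (permutation p 0.63 to 0.913). On Jaccard dissimilarity it differed for Salt against CTL (permutation p = 0.0002) and over all 4 groups (permutation p = 0.032). On genera in place of OTUs, S+B against CTL explained 13.5% (permutation test, adjusted p = 0.0586) and B against S+B 6.86% (adjusted p = 0.378), so neither passed. Within S24-7 the OTUs differed between CTL and every other group, a comparison chosen after the data were seen. The 10 commonest S24-7 OTUs of CTL held 82.8% ± 5.06 of the family in CTL, 27.4% ± 5.01 in Salt, 9.06% ± 4.88 in S+B and 10.8% ± 1.62 in B. In the other direction the contrast was smaller: the 10 commonest of S+B held 65.1% ± 11.8 of the family in S+B and 40.9% ± 6.29 in CTL, those of B 61.3% ± 5.02 in B and 40.6% ± 7.14 in CTL, and those of Salt 60.2% ± 5.38 in Salt and 47.6% ± 5.6 in CTL. OTU2631, the 1 OTU common to all 4 sets, held 36.3% ± 7.11 of the family in CTL, 15.9% ± 6.00 in Salt, 5.49% ± 3.53 in S+B and 4.73% ± 2.27 in B.

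**Figure D4:**
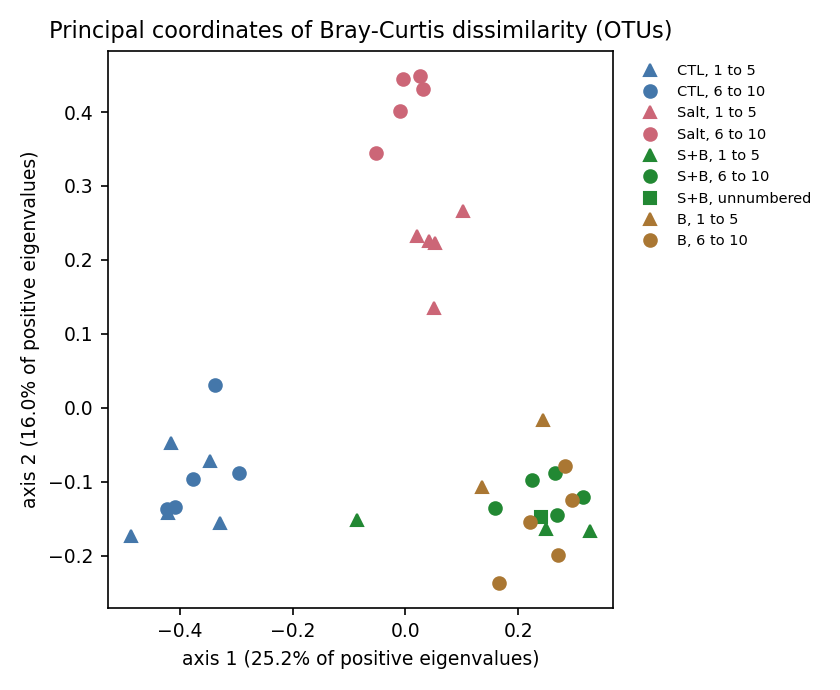
Principal coordinates of Bray-Curtis dissimilarity between OTU profiles; each point is a sample, coloured by group, with the symbol giving its number (1 to 5, 6 to 10 or unnumbered). Axis 1 holds 25.2% and axis 2 16.0% of the variation, and the Salt samples 1 to 5 and 6 to 10 form separate sets.

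**Figure D5:**
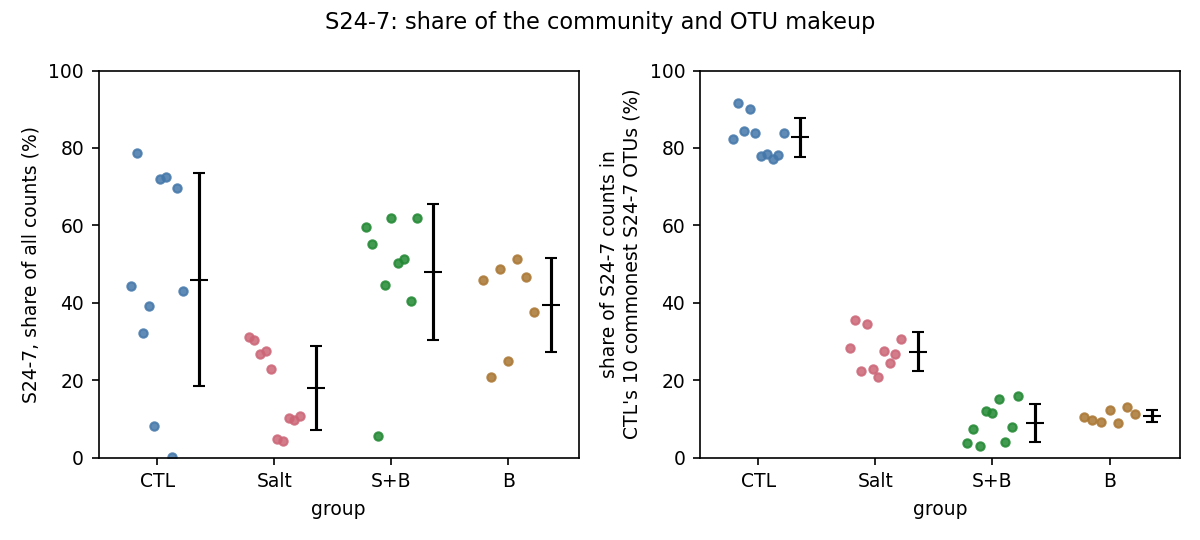
S24-7 as a share of all counts (left, %) and the share of S24-7 counts held by the 10 commonest S24-7 OTUs of CTL (right, %), per sample by group, with bars for mean and SD. S+B and B had S24-7 shares of 47.9% and 39.5% beside 46.0% in CTL. The OTUs chosen as commonest in CTL held 9.06% and 10.8% of the family in S+B and B. Those commonest in S+B and in B held 40.9% and 40.6% of it in CTL. Most of that was OTU2631 (36.3%), found in every group's set.

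Whether buckwheat moved genera that salt changed back towards CTL was examined on the 2 log2 fold changes. In B, a move back can also stem from the end of the high-salt diet. Turicibacter, Parabacteroides, Rikenellaceae, S24-7 and Comamonadaceae changed in Salt and the opposite way in both S+B and B, without a call against CTL. Lachnospiraceae and Streptococcus did so in S+B and YS2 in B, and whether the groups differ was not tested. Sutterella also moved back in both, without a call against CTL in S+B and above CTL in B (2.85, adjusted p = 0.000285). Devosia, counted as moving back, ended above CTL (9.01 in S+B and 8.03 in B), and its 22 CTL counts lay in 1 sample. Butyricimonas, RF32, Desulfovibrio and Faecalibacterium moved further from CTL in both. A missing call is no proof of return, and several calls here ended without single samples (above). Of genera changed in both steps, 10 moved back in S+B (8 without a call) and 4 further. In B, 8 moved back (6 without a call) and 7 further. Over all 65 groups the fold changes of Salt against CTL and S+B against Salt correlated at r = -0.20, and those of B at r = -0.17. Because both share the Salt samples, unchanged groups gave r = -0.47 and -0.44 on average in 100 simulations (range -0.737 to -0.054 and -0.768 to -0.135). Both correlations lay inside these ranges, and genera are not independent replicates. The covariance was -2.75 in S+B and -2.52 in B against simulated means of -0.47 in each, a difference of -2.28 and -2.05. Fold changes varied less in unchanged groups, so neither their r nor their spread of covariance is a yardstick. With the Salt samples split so that the comparisons shared none, the mean correlation was -0.11 and -0.08, and the mean covariance was -1.53 (range -2.48 to 3.25) and -1.12 (range -2.59 to 4.41), so both ranges spanned 0. Overlaps of calls differed. Unchanged groups give almost no calls, so their overlap of 0 is no yardstick. Split Salt samples gave shorter lists, so the value for independent lists of those lengths is added last. There were 7 genera lower in Salt and higher in S+B, where independent lists give 4.71, unchanged groups 0 and split Salt samples 1.65 (last value 2.75). For B, 5 were lower in Salt and higher in B (3.4, 0, 1.4 and 2.22). In the other direction, 3 genera were higher in Salt and lower in S+B (2.03, 0, 2.06 and 1.29) and 3 higher in Salt and lower in B (2.58, 0, 2.57 and 1.65). S+B and B shared more, 11 genera higher than in Salt (3.6, 0, 8.39 and 2.07) and 10 lower (2.37, 0, 7.38 and 1.83). With split samples, the overlaps of genera lower in Salt and higher with buckwheat lay below the last value, and the others above.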

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

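The tests of 1 source, label numbers, exchanged samples and housing, and the counts of other splits, were chosen after seeing the results. A sample was singled out where its gap to the nearest other sample, over the range of its group, passed Dixon's 95% critical value. This held in 49 of 228 groups of values. Chance at 1 in 20 (11.4) is no yardstick, as several shares were 0 in the rest of the group. Of the 49, 16 were in S+B 5, 11 in Salt 6, 6 in B 5 and 5 in S+B 10. Shares of 1 sample sum to a whole and are not independent. Each share has its 95% Wilson interval and the nearest extreme of its group's other samples, where 0% allows up to 3 counts of a sample's total.

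In S+B 5, Proteobacteria took 52.2% (51.5% to 52.8%; 4.02%), with Devosia at 34.5% (33.9% to 35.2%; 1.35%), Halomonas at 6.91% (6.58% to 7.25%; 0.277%) and Aminobacter at 3.41% (3.18% to 3.66%; 0.181%). Phyllobacteriaceae took 2.29% (2.10% to 2.5%; 0.111%) and Rhizobiales 2.28% (2.09% to 2.49%; 0.0826%). The salt-tolerant list stood at 7.26% (6.93% to 7.61%; 0.399%), and the kit and water list at 0.646% (0.549% to 0.761%; 0.0286%). Ochrobactrum took 0.400% (0.325% to 0.493%; 0.0350%), Enterobacteriaceae 0.0956% (0.0625% to 0.146%; 0.0159%), Stenotrophomonas 0.0364% (0.0184% to 0.0718%; 0.00338%) and Erwinia 0.00455% (0.000803% to 0.0258%; 0%). Low values were those of Bacteroidetes at 7.78% (7.43% to 8.14%; 48.9%), gut Bacteroidales at 7.58% (7.24% to 7.94%; 47.7%), S24-7 at 5.52% (5.23% to 5.83%; 40.5%) and Clostridiales at 2.17% (1.98% to 2.37%; 8.22%).

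In Salt 6, Turicibacter took 47.4% (46.8% to 48.1%; 1.04%) and the fibre and mucin list 48.8% (48.2% to 49.5%; 5.06%). Ochrobactrum took 4.64% (4.37% to 4.93%; 0.472%), Phyllobacteriaceae 0.329% (0.262% to 0.413%; 0.0476%), Rhizobiales 0.212% (0.159% to 0.282%; 0.0365%) and Erwinia 0.0316% (0.0153% to 0.0651%; 0.00794%). Short-chain fatty acid producers were low at 4.29% (4.03% to 4.56%; 7.70%), as were Oscillospira at 2.87% (2.66% to 3.10%; 5.09%) and Ruminococcaceae at 2.75% (2.54% to 2.97%; 4.97%). Its Shannon index was 3.26, where the other Salt samples had at least 4.67, and it held 582.2 OTUs, where they had at least 747.2.

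In B 5, gut Bacteroidales were low at 22.7% (22.1% to 23.3%; 41.5%), and Clostridium was high at 0.140% (0.0975% to 0.201%; 0.0262%). It held the group's counts of Helicobacter at 0.00966% (0.00265% to 0.0352%; 0%), Flexispira at 0.00483% (0.000852% to 0.0273%; 0%), both as a list at 0.0145% (0.00493% to 0.0426%; 0%), and Desulfovibrio at 0.00483% (0.000852% to 0.0273%; 0%). In S+B 10, Helicobacter and relatives stood at 0.0236% (0.0115% to 0.0488%; 0.00277%), with Helicobacter at 0.00675% (0.00185% to 0.0246%; 0.00277%) and Flexispira at 0.0169% (0.00721% to 0.0395%; 0%), Desulfovibrio at 0.145% (0.108% to 0.196%; 0.0227%) and Klebsiella at 0.0169% (0.00721% to 0.0395%; 0%).

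Clostridiales were low in B 7 at 1.67% (1.53% to 1.82%; 7.46%) and S24-7 in CTL 8 at 0.290% (0.234% to 0.359%; 8.28%), where Devosia stood at 0.0769% (0.0508% to 0.116%; 0%). Verrucomicrobia were high in Salt 2 at 2.93% (2.67% to 3.21%; 0.760%) and in CTL 7 at 0.175% (0.131% to 0.233%; 0.0707%), and plant organelle DNA was high in Salt 4 at 1.76% (1.60% to 1.93%; 0.110%). The remaining values rested on few counts: Allobaculum in CTL 3 at 0.0181% (0.00773% to 0.0424%; 0.00699%), Anaerostipes in CTL 9 at 0.0148% (0.00576% to 0.0381%; 0.00362%), Coprobacillus in CTL 10 at 0.0514% (0.0317% to 0.0835%; 0.0127%), and Butyricimonas and RF32 in CTL 4, each at 0.00379% (0.000669% to 0.0215%; 0%).

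Devosia, Halomonas, Aminobacter, Nesterenkonia, Phyllobacteriaceae and Rhizobiales peaked together in S+B 5 and in B 5, and the first pair had counts in 16 of 16 buckwheat samples. Across these the log2 ratio of Halomonas to Devosia had an SD of 0.729 against 3.38 for log2 Devosia (median 0.225 Halomonas counts per Devosia count, 0.0588 to 0.429), which is consistent with 1 outside source for that pair; the other 4 taxa were not tested in this way. The share of the 6 taxa followed that of the listed kit and water genera, the first of 2 relations examined (Spearman's rho 0.923, 95% bootstrap interval 0.735 to 0.988, Pearson's r 0.936, each with permutation p = 1e-05, the smallest possible, and adjusted p = 2e-05; r 0.912 without the 2 farthest samples; rho 0.95 in S+B and 0.815 in B, exact permutation p = 0.000353 and 0.0381), so background DNA of reagents or water stays open, although that list had medians of 0.0166% in S+B and 0.00306% in B against 0.0496% in Salt (means 0.0850%, 0.0415% and 0.261%, or 0.0148%, 0.0138% and 0.101% without S+B 5, B 5 and Salt 6). The relation to plant organelle counts was not clear (rho 0.309, interval -0.229 to 0.696, permutation p = 0.245, adjusted p = 0.245; r 0.257, permutation p = 0.337, adjusted p = 0.337, and 0.235 without the 2 farthest samples; rho 0.0333 in S+B and 0.286 in B), so plant material of the diet in the stomach cannot be told apart from other sources with 16 samples. Growth of these bacteria in mice fed buckwheat stays open as the biological explanation and was not tested.

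The Salt samples 1 to 5 and 6 to 10 formed separate sets, a split that explained 33.1% of the Bray-Curtis variation and was the strongest of all splits into 5 and 5. A batch that follows the label number in every group was argued against by CTL, where 61 splits, 48.4% of all, were as strong as the same one (10.5%), as were 16 of 56 in S+B and 3 of 21 in B. An exchange of Salt 1 to 5 with a buckwheat group was argued against by 0 counts of Devosia and Halomonas among 110097 (limit 0.00272%). Total counts were 22019 ± 4802 (SD, n = 5) and 21069 ± 1427 (n = 5). Housing or handling shared by part of the Salt group cannot be told apart from other causes, since the labels tie no cage or day to the numbers, and no biological explanation was tested.

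S24-7 took 46.0%, 47.9% and 39.5% of the counts in CTL, S+B and B. Its OTUs differed from CTL by 62.9% of within-family variation in Salt, 71.7% in S+B and 75.5% in B (permutation, adjusted p 0.0002 to 0.00024). Rare OTUs or depth were argued against by the 38 OTUs of at least 1% of the family thinned to 83 counts, which gave 66.1% for S+B (permutation p = 0.0001, the smallest possible). Buckwheat as the whole cause was argued against by Salt samples, which had none and differed from CTL as well. They lay narrowly farther from CTL (mean dissimilarity 0.666) than from S+B (0.603, 7 of 10 samples) or B (0.546, 10 of 10). The smaller gap of 0.0639 passed the SD of 0.0595 between Salt samples and its own SD of 0.0621. The rule was a gap over 1 SD, not a test, and the SD was settled after the values were seen. A part played by buckwheat stays open, since S+B and B differed from Salt by 44.5% and 40.3% of that variation. The high-salt diet eaten by Salt, S+B and B is a candidate explanation, untested against mice that came with other OTUs, since the labels give no cages.

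Whether chance gives as many calls was examined with 100 splits of the samples per comparison, the real one included. Only 1 of 100 splits, the real one, reached the real number of genera in Salt against CTL (29, highest other 13), S+B against Salt (29, highest other 17), B against Salt (27, highest other 16), S+B against CTL (32, highest other 5) and B against CTL (31, highest other 9), or of OTUs in Salt against CTL (209, highest other 27), S+B against Salt (152, highest other 30) and B against Salt (147, highest other 28). Random splits of single samples thus rarely give such counts, with 1 of 100 the smallest share possible. They cannot show whether cages or handling shared by samples gave them, since the labels state no cages. In B against S+B, 31 of 100 splits called at least the real 3 genera, so chance cannot be excluded there. The highest other called 20, several times the real count, which points to a structure of the samples that was not tested further.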

How the results depend on the processing

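Leaving out samples, the number sets 1 to 5 and 6 to 10 and their blocks, and the sets without the 4 set-aside samples (CTL 8, Salt 6, S+B 5 and B 5) or the unnumbered S+B sample were chosen only after the results were seen. For diversity, composition, movement back towards CTL and the numbers of genera, OTUs, lists and phyla that passed, 204 values kept their direction and side of the threshold or stayed within 1.5 times or 1 SD, 24 moved further, 5 lost the call and 2 gained one. For single lists and phyla, 150 values did so, 9 lost the call and 9 gained one. For genera and OTUs named in the text, 1271 values did so, 179 lost the call, 26 gained one and 10 reversed. With single samples left out these numbers were 2080, 124, 31 and 2. Jaccard and Aitchison dissimilarity, organelle OTUs kept and the fit of the compared groups alone moved no count of genera and no composition result past these limits. The cause was not tested except where stated.

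With no filter on low counts more taxa were tested, and more changed: 84, 46, 52, 91, 76 and 11 genera in Salt against CTL, S+B against Salt, B against Salt, S+B against CTL, B against CTL and B against S+B, and 808, 512 and 459 OTUs in the first 3. The number sets hold fewer samples. Numbers 1 to 5 gave 1 genus in S+B against Salt and 1 in B against Salt, 12 and 10 for S+B and B against CTL and 0 for B against S+B, and numbers 6 to 10 gave 12 for Salt against CTL and 5 for B against S+B. The centred log ratio with group and number set as a random block gave 17 for B against Salt and 5 for B against S+B. The 3 genera of B against S+B became 8 with DESeq2 and 5 with library size, with the centred log ratio or without the 4 set-aside samples. With single samples left out they ranged from 3 to 7, with 7 without S+B 5 or B 10, 6 without B 5 or B 6 and 5 without B 2, B 7 or B 8. The other counts of genera ranged over 24 to 35, 25 to 32, 25 to 31, 28 to 37 and 29 to 37 in the same order, and those of OTUs over 189 to 210, 138 to 156 and 127 to 154.

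Without the 4 set-aside samples the Shannon index differed by -0.582 in S+B against Salt (exact permutation test, adjusted p = 0.00296) and by -0.552 in B against Salt (adjusted p = 0.0107), both past the threshold. Observed OTUs of B against CTL then differed by 86.2 (adjusted p = 0.0676). Without rarefaction the difference in observed OTUs was -80.8 in S+B against Salt (exact permutation test, adjusted p = 0.189) and -107 in B against Salt (adjusted p = 0.0873), on totals that were higher in S+B and B than in Salt. Genus-level dissimilarity gave 13.5% for S+B against CTL and 6.86% for B against S+B (permutation tests, adjusted p = 0.0586 and 0.378).

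In S+B against Salt, leaving out single samples took Rhizobiales from -0.54 to 5.94 and Phyllobacteriaceae from -0.90 to 5.93, the lowest without S+B 5 and the highest without Salt 6. Phyllobacteriaceae stood at -0.11 among numbers 6 to 10, and Anaerostipes at -0.26 and Desulfovibrio at 3.95 among numbers 1 to 5. In B against Salt, numbers 1 to 5 gave -1.42 for Coprobacillus, -3.49 for Akkermansia, -2.15 for RF32, -1.54 for Parabacteroides, 2.58 for Flexispira and 2.57 for Desulfovibrio, with 2 B samples, and numbers 6 to 10 gave 1.17 for Prevotellaceae.

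In 5 of the 6 comparisons the label numbers do not pair the samples, with a median correlation near 0 between samples of the same number. In B against S+B that median was 0.386, against -0.015 for other numbers, and 4 of 7 pairs passed 0.1. A link by number stays open there. The closest partner carried the same number for 0, 0, 0, 1, 1 and 3 samples. With the replicate number as a block, 30, 25, 20, 34, 31 and 3 genera changed, and the correlations of movement back towards CTL were -0.036 in S+B and 0.019 in B and the covariances -0.429 and 0.242. Depth limits what the smallest shares can show, since 1 count is 1 of 15150 to 38426.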

Other observations

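Thermus, a genus of hot water that grows far above body temperature, was singled out after its values were seen and was not among the 65 groups tested. It had no count in CTL or Salt, which allows up to 0.00104% and 0.00139%. It had 217 counts in 8 of 9 S+B samples and 1331 in 5 of 7 B samples, at least 59.6-fold and 473-fold more than in Salt (floor of 3 counts over the group). Without S+B 10 and B 5 these bounds were 19.0-fold and 16.6-fold. B 5 held most of it, at 6.26% (95% Wilson interval 5.94% to 6.60%), followed by S+B 10 at 0.550% (0.472% to 0.641%) and S+B 5 at 0.141% (0.0994% to 0.200%). Nesterenkonia, a salt-tolerant actinobacterium, had no count in CTL and was at least 128-fold more abundant in S+B and 129-fold in B, or 18.7-fold without S+B 5 and 60.3-fold without B 5.

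Anaeroplasma and Peptococcaceae, outside the rule for named taxa, and the levels of Butyricimonas over all groups were also chosen after their values were seen. Anaeroplasma, wall-less anaerobes of the gut, had no count in CTL and counts in 10 of 10 Salt samples at 0.0553% ± 0.0465, at least 56.4-fold more. It was found in 4 of 9 S+B and 4 of 7 B samples. Butyricimonas took 0.0259% ± 0.0274 in Salt (n = 10), 0.164% ± 0.101 in S+B (n = 9) and 0.235% ± 0.107 in B (n = 7), and had 1 count in all of CTL. Peptococcaceae took 0.00407% ± 0.00661 in CTL, 0.0330% ± 0.0252 in Salt, 0.0295% ± 0.0253 in S+B and 0.0836% ± 0.0426 in B.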
